A study of Daphnia magna with 9 samples.

How the data were processed

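Whole adults of Daphnia magna clone A were sequenced after bisulfite conversion (MethylC-seq, per the labels' protocols), with 9 libraries from 3 generations and 3 dose classes and 1 library in each group. Groups were taken from the sample titles. For the F0 control the title says control, while other labels of that sample speak of exposure as they do for its whole generation; the title was followed.

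The authors deposited whole-number counts of methylated and unmethylated reads for each CpG cytosine on either strand, with the position and trinucleotide context. Reads were processed with Bismark 0.16.3, per the submitters' processing notes, and the file names say that reads were trimmed, paired and deduplicated. The genome build is not given in the sources used here, and coordinates are on the sequences named in the deposited files, 27645 of which carry a CpG. All 9 libraries list the same 8882200 cytosines. Of these, 2120 (0.0239%) have no partner cytosine on the other strand and were not used. No pair of libraries holds identical values.

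The counts of the 2 strands were summed for each of 4440040 CpG dyads. A dyad was tested if it had 10 or more reads in each of the 9 libraries and no more than the 99.9th percentile of coverage in any library, which left 3658342 dyads. Requiring 10 reads means that a level of a single dyad has a wide interval, and that levels of clusters and of all dyads are much more precise: clusters held a median of 109 to 143 calls per library. A methylated dyad has a pooled level of 10% or more over the reads of all 9 libraries, so that deeper libraries weigh more. Single dyads were compared between libraries within these 40879 methylated dyads. A cluster holds 3 or more methylated dyads with gaps of at most 100 bp.

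The background rate of a library is its share of methylated calls at dyads whose pooled level in the other 8 libraries is under 2%. It holds failed conversion, base errors and any sparse methylation. Dyads were called methylated per library with a one-sided binomial test against that rate and Benjamini-Hochberg adjustment at 0.05. Mean differences of levels between dose classes, matched on generation, and between generations, matched on dose rate, were tested with two-sided exact sign-flip permutation tests, which cannot go below 0.25 with 3 differences. Pairs of libraries were compared with two-sided Fisher's exact tests, adjusted within each pair at 0.05, with a difference of 20 points or more required for a dyad and 10 points or more for a cluster. Positions of a library between 2 others, and the move of neighbouring dyads, have 95% intervals from 1000 bootstrap draws of scaffolds. The 3 pairs of controls and all other pairs were set beside them. The number of clusters shared by lists drawn independently is the product of the 2 list lengths, within a direction, divided by the 4874 clusters.

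Contrasts over all 9 libraries used edgeR 4.0.16 (glmQLFit and glmQLFTest) on methylated and unmethylated counts per cluster, with a term for each library and terms for generation and dose rate on the methylated counts, a common dispersion (0.0145) and 4 residual degrees of freedom. Dose rates were compared with generation as a block and generations with dose rate as a block. The alternative tool was limma 3.58.1 on log2 of the ratio of methylated to unmethylated counts, with 2 added to each. Log2 odds ratios are on the scale of that ratio. Adjusted p-values are Benjamini-Hochberg values over clusters, and a threshold of 0.05 was used. Other computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and R 4.3.3, with random seed 11.

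The tests were tested on simulated data with the real coverage, 200 clusters changed by 10, 20 or 30 points, and, for the model, a spread of 0.2 on the natural logit scale between libraries. This spread was assumed, and the recovered shares hold for it. For 41.3 mGy/h against control edgeR called 11 unchanged clusters and limma 12 among 4874. Fisher's test for F0 41.3 mGy/h against control recovered 21.4%, 71.2% and 95.8% of the changes of 10, 20 and 30 points with 3 unchanged clusters called, and for F2 41.3 mGy/h against control 17.9%, 61.6% and 90.1% with 2. In these simulations no reads were shared between dyads, and for Fisher's test there was no spread between libraries. The few unchanged clusters called by Fisher's test hold for that setting and do not measure false calls in the real pairs. The binomial test recovered 99.2% of methylated dyads at the coverage of the F0 control.

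Before the data were examined, the groups, tests, thresholds, naming rule and alternatives were fixed, apart from those named as added later. Alternatives were coverage minimums of 5 and 20, no upper coverage limit, equal weights for dyads, thinning every dyad to 10 reads, pooled levels of 5% and 20%, gaps of 50 and 200 bp, 5 or more dyads per cluster, other sizes of difference, limma, models without the block, each library left out in turn, and F2 and F3 alone. Subtracting the background rate from the unweighted or the read-weighted level, equal weights within the methylated dyads, leaving out both exposed F3 libraries, and leaving out each generation or dose class from the differences in levels were added after seeing the data, and the test of the model on simulated data was written after the model had first been run.

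Clusters are named by position. For each pair the rule names the 3 higher and 3 lower clusters with the largest difference, and those shared by F2 and F3 up to 10 for each direction. For each contrast over all libraries it names up to 12 higher and 12 lower clusters past the threshold, or the 5 with the smallest p where fewer than 5 pass. Of the clusters so named the text prints a part, with the largest differences, those that recur in another list and those with the smallest p. Clusters on scaffold01581 and scaffold00243, called only with libraries left out, were named after their values were seen. The gene table at hand belongs to another assembly than the deposited coordinates, so clusters were not assigned to genes, and tests of the 21 gene lists fixed beforehand and of DNA methyltransferase and TET genes were not run.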

Results

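DNA methylation was measured by whole-genome bisulfite sequencing in whole adults of the water flea Daphnia magna, clone A. Bisulfite treatment converts unmethylated cytosines, so that a cytosine still read as cytosine counts as methylated. In the design the F0 generation was irradiated with gamma rays for 25 days, from the egg to adulthood, and the generations after it were not irradiated. Libraries came from F0, F2 and F3, each with a control, a library labelled 41.3 mGy/h and a library labelled 0.0065 mGy/h. In F2 and F3 the dose rate therefore names the exposure of the F0 ancestors. Each of the 9 groups held 1 library, so no group had replicates. The libraries held between 115459907 calls (F3 0.0065 mGy/h) and 179221402 calls (F0 0.0065 mGy/h) at 8882200 CpG cytosines, and the median CpG dyad, the cytosines of both strands summed, had 22 to 34 calls. The comparisons below ask whether methylation differed with the dose rate of the F0 ancestors, whether such differences recurred in generations that were not irradiated, and whether the generations differed. Intervals of levels and shares are 95% exact binomial intervals and cover counting error only. They treat calls as independent. A read can cover several dyads, so intervals of levels over several dyads are too narrow.

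Methylation was sparse and concentrated in short clusters. Of 3658342 tested dyads, 40879 (1.12%) had a level of 10% or more over all libraries pooled, and 98.5% had a level under 2%. Of the methylated dyads, 23004 (56.3%) had a pooled level of 80% or more. Another 5270 dyads lay between 40 and 50%, where the distribution had a lower maximum. A tested dyad within 100 bp downstream of a methylated dyad was itself methylated in 78.9% of cases, against 0.161% after an unmethylated dyad. Joining neighbouring methylated dyads gave 4874 clusters, which held 21745 dyads (53.2% of the methylated ones) and spanned a median of 119 bp. The landscape was shared between the libraries: 38994 of the 40879 methylated dyads (95.4%) were called methylated in each of the 9 libraries.

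**Figure D1:**
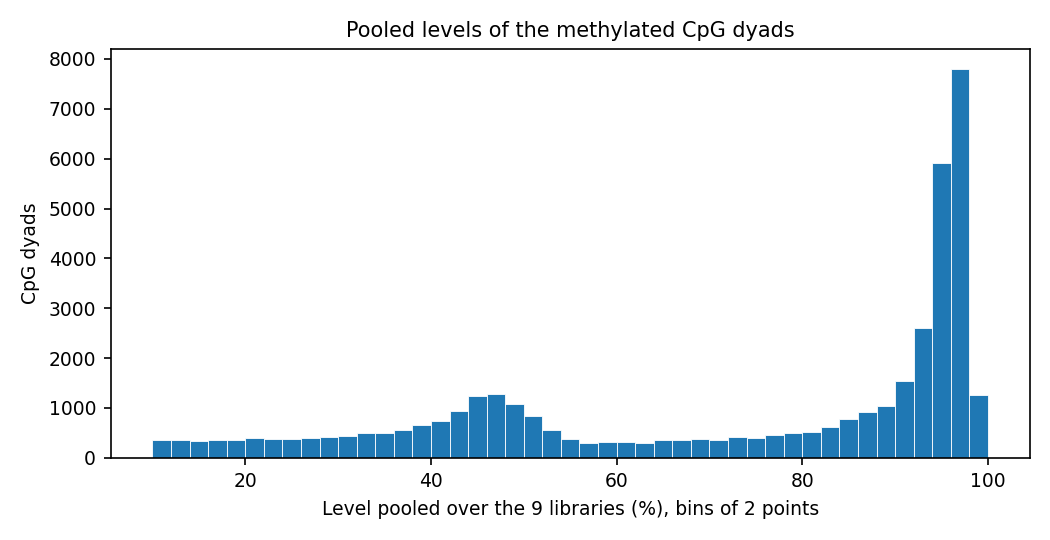
Number of CpG dyads (vertical axis) by the methylation level pooled over the 9 libraries (horizontal axis, percent, bins of 2 points), for the 40879 methylated dyads. Most dyads lie at 80% or more, and 5270 form a lower maximum between 40 and 50%.

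Across dose rates the overall level differed little. The read-weighted level of all tested dyads was 1.13% in the F0 control, and the F0 libraries at 41.3 and 0.0065 mGy/h differed from it by -0.0366 and -0.0824 points. In F2 the level was 1.37% in the control, 1.19% at 41.3 mGy/h and 1.22% at 0.0065 mGy/h, and in F3 1.26%, 1.23% and 1.33%, in the same order. The 41.3 mGy/h libraries lay below their control in each of the 3 generations, by a mean difference of -0.0861 points (two-sided exact sign-flip permutation test, p = 0.25, the smallest p that 3 differences can give). At 0.0065 mGy/h the mean difference was -0.0546 points, with F3 going the other way (exact p = 0.5). Both differences depended on how reads were distributed: with every dyad weighted equally they were -0.0115 and -0.0183 points (exact p = 0.75 for each), and F3 lay above its control at 41.3 mGy/h too. Without F2, whose control had the highest level, they were -0.0382 and -0.00687 points, and without F3 the second was -0.116 points. The F2 control and the F3 0.0065 mGy/h library, with the highest levels, also had the most reads at methylated relative to other dyads, 1.16 and 1.12 times as many, against 0.924 to 0.991 in 6 of the other libraries.

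Levels at the methylated dyads were also close to each other in all libraries. Over the same 40879 dyads the read-weighted level ran from 69.1% in the F0 control (interval 69.0 to 69.2) to 70.9% in the F2 control (70.9 to 71.0). The mean difference from control was -0.560 points at 41.3 mGy/h and -0.662 points at 0.0065 mGy/h (exact sign-flip permutation test, p = 0.5 for each, 1 of the 3 generations positive in each). Both means rested on F2, with differences of -1.55 and -1.80 points, and were -0.0664 and -0.0945 points without it, -0.883 and -1.30 points without F0, and -0.229 and -0.328 points with every dyad weighted equally. Between 41788 (F2 41.3 mGy/h) and 42448 (F0 41.3 mGy/h) dyads were called methylated per library. The mean difference in this number was -101 dyads at 41.3 mGy/h and -30.7 dyads at 0.0065 mGy/h (exact p = 0.75 and 1). Thinning every dyad to 10 reads turned both signs, to 1249 and 1202 more dyads than in the controls, and so did leaving out F3, to 11.5 and 129.5 more dyads. Thinned, a call needed 2 methylated reads in the exposed F0 libraries and 3 in all other libraries.

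The F2 and F3 libraries had a higher overall level than the F0 libraries. The mean level was 1.09% ± 0.0413 (SD, n = 3 libraries of different dose rates) in F0, 1.26% ± 0.0971 in F2 and 1.27% ± 0.0549 in F3. Matched on dose rate, F2 exceeded F0 by 0.166 points and F3 exceeded F0 by 0.181 points, each in 3 of 3 dose rates (exact sign-flip permutation test, p = 0.25, the smallest possible). The background rate, which is the share of methylated calls at dyads with a pooled level under 2%, differed in the same direction, with 0.359% ± 0.0349 in F0, 0.445% ± 0.0118 in F2 and 0.465% ± 0.0187 in F3. With every dyad weighted equally the level differed by 0.0841 points for F2 and 0.105 points for F3, and after the background rate was also subtracted the differences were -0.00197 points for F2 and -0.000582 points for F3. Subtracted from the read-weighted level instead, it left 0.0795 and 0.0747 points. At the methylated dyads F2 exceeded F0 by 0.474 points and F3 exceeded F0 by 0.374 points (exact p = 0.75 and 0.5), and both differences changed sign, to -0.179 and -0.0153 points, with every dyad weighted equally. Without the control libraries they were -0.200 and 0.0881 points. The number of dyads called methylated differed from F0 by a mean of -337 in F2 and -192 in F3, where 1 of the 3 dose rates was positive (exact p = 0.25 and 0.5). With each dose class left out in turn the differences ran from -472.5 (without 0.0065 mGy/h) to -175.5 (without 41.3 mGy/h) in F2 and from -341.5 (without the controls) to -79.5 (without 41.3 mGy/h) in F3. With a level of 20% and no test, the F2 difference changed sign, to 15.3 dyads. With dyads thinned to 10 reads the differences were -2623 and -2631, with 1 of the 3 dose rates positive in each. Thinned, 2 methylated reads sufficed for a call in the exposed F0 libraries, and 3 were needed in all other libraries. These 2 differences are therefore no measure of a loss of methylated dyads.

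**Figure D2:**
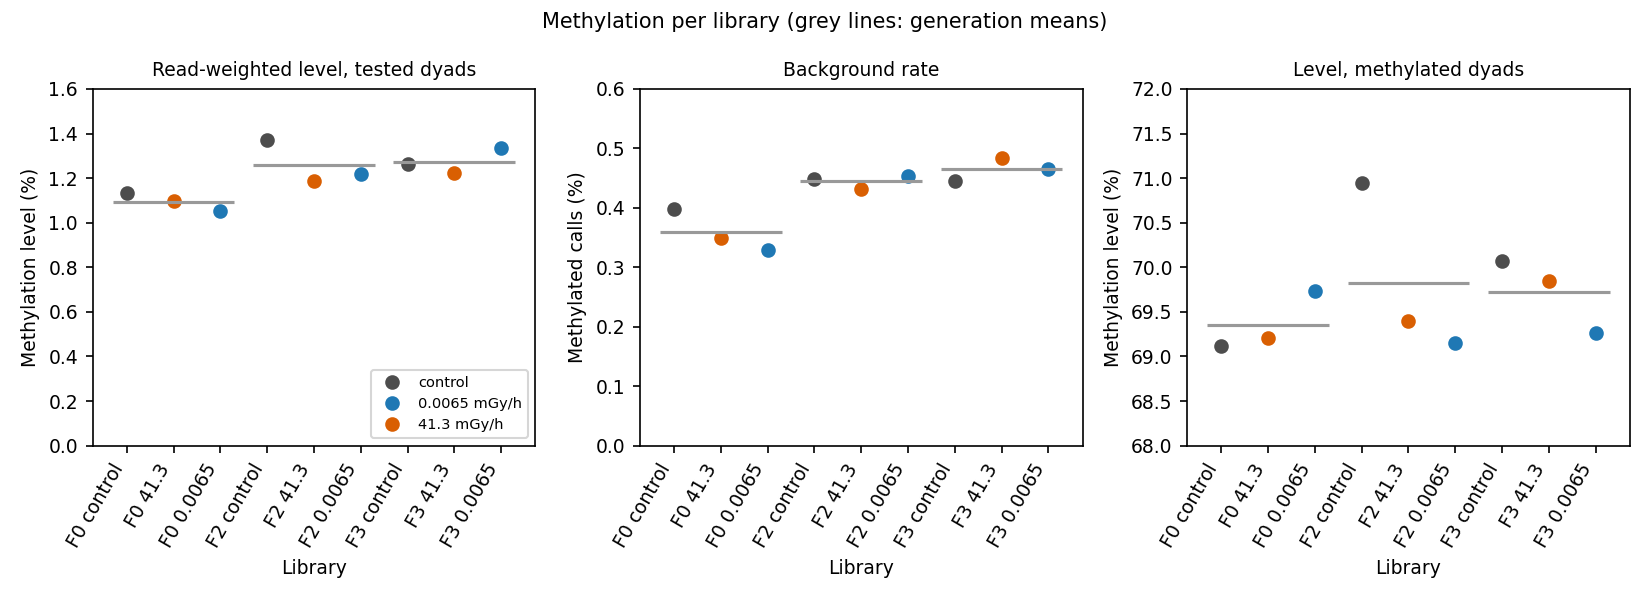
Read-weighted methylation level of all tested dyads (left), background rate (middle) and level of the methylated dyads (right, axis from 68 to 72%), all in percent, for each of the 9 libraries (horizontal axis), coloured by dose rate, with grey lines at the generation means. F2 and F3 lie above F0 in the left and middle panels, and the levels of the methylated dyads span 69.1 to 70.9%.

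In the irradiated generation, F0, few clusters differed between exposed and control libraries, some of them strongly and in both directions. At 41.3 mGy/h, 58 of the 4874 clusters (1.19%) differed from control by 10 points or more (29 higher, 29 lower). At 0.0065 mGy/h 32 (0.657%) did (19 higher, 13 lower), the lowest count of all 36 pairs of libraries. Pairs of controls gave 40 to 89. The largest increase at 41.3 mGy/h was in a cluster of 6 dyads on scaffold02452, positions 19789 to 19817. Its level was 41.1% (90 calls) in the control and 81.2% (69 calls) in the exposed library (Fisher's exact test, adjusted p = 0.000210). A read can cover all 6 dyads, so the reads may be far fewer than the calls. The binomial interval of the 81.2%, 69.9 to 89.6, is then too narrow. The largest decrease was on scaffold00763, positions 184624 to 184705, from 85.2% (115 calls) to 49.0% (155 calls; adjusted p = 1.85e-06). This cluster was also the largest decrease at 0.0065 mGy/h, at 51.5%, and its level in the F2 and F3 controls was 41.0% and 50.3%, so that the F0 control stood apart from the other 8 libraries there. On scaffold00781, positions 368453 to 368511, the level was 48.1% in the F0 control, 75.2% and 79.0% in the exposed F0 libraries, and 71.6% and 72.7% in the F2 and F3 controls. The largest increase at 0.0065 mGy/h was on scaffold03124, positions 1455776 to 1455868, from 38.5% (52 calls) to 76.6% (64 calls; adjusted p = 0.0122), next to 76.3% in the F3 control. Of the 12 F0 differences named by the rule, the 3 largest in each direction at each dose rate, 5 left the exposed library inside the range of the 3 controls. A cluster named at both dose rates counts for each. Both comparisons used the same F0 control library.

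In F2, whose animals were not irradiated, more clusters were lower than higher in the libraries of exposed ancestry. At 41.3 mGy/h 69 clusters differed (22 higher, 47 lower) and at 0.0065 mGy/h 84 did (28 higher, 56 lower), and at 20 points the counts were 15 higher and 19 lower at 41.3 mGy/h and 13 higher and 29 lower at 0.0065 mGy/h. Both comparisons used the same F2 control library, which had the highest level of the methylated dyads. The largest increase at 41.3 mGy/h was on scaffold01800, positions 105719 to 105812, from 52.3% (65 calls) to 91.4% (58 calls; Fisher's exact test, adjusted p = 0.000446), and the largest decrease on scaffold00512, positions 1364333 to 1364422, from 59.0% (144 calls) to 19.8% (86 calls; adjusted p = 6.86e-06). In neither cluster did any other library reach the level of F2 41.3 mGy/h; on scaffold01800 the nearest was the library labelled F3 0.0065 mGy/h, at 72.1%. At 0.0065 mGy/h the largest increase was on scaffold02385, positions 471717 to 471786, from 29.1% (79 calls) to 69.7% (89 calls; adjusted p = 0.000115). The largest decrease was on scaffold00725, positions 362247 to 362323, from 58.7% (155 calls) to 20.8% (168 calls; adjusted p = 8.54e-09). For all 12 F2 differences named by the same rule the exposed library lay outside the range of the 3 controls. The clusters were picked for a large difference from 1 of these controls in the same reads. In addition, 0 dyads differed between the F2 and F3 controls. This count is therefore no measure of an effect of dose rate.

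In F3 the library labelled 41.3 mGy/h differed from the F3 control in 96 clusters (56 higher, 40 lower), and the library labelled 0.0065 mGy/h differed from the same control in 62 (29 higher, 33 lower). The largest increase in the former was on scaffold00725, positions 748965 to 749021, from 18.8% (144 calls) to 50.8% (128 calls; Fisher's exact test, adjusted p = 2.08e-05), and the library labelled 0.0065 mGy/h stood at 51.9% in the same cluster. The largest decreases in the library labelled 41.3 mGy/h were on scaffold00196, positions 1306 to 1353, from 69.3% to 36.6% (adjusted p = 0.00294), where the F0 control stood at 34.4%, and on scaffold00915, positions 972518 to 972556, to 21.9% (201 calls), a difference of -32.1 points (adjusted p = 1.63e-08). On scaffold00915 the F2 0.0065 mGy/h library was similarly low, at 17.5%, while the F2 41.3 mGy/h library stood at 41.0%. On scaffold02581, positions 74094 to 74214, the levels were 24.1% in the library labelled F3 41.3 mGy/h, 25.2% in F2 0.0065 mGy/h and 44.4% or more in the other 7 libraries. In the library labelled F3 0.0065 mGy/h the largest increase was on scaffold00868, positions 1408166 to 1408211, from 24.7% (97 calls) to 59.8% (92 calls; adjusted p = 0.000473). Of the 12 F3 differences named by the same rule, 1, on scaffold00196, left the exposed library inside the range of the 3 controls. The pick limits this count as it does in F2.

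These tests compare libraries and not conditions, and pairs of controls gave similar numbers. Between the F0 and F2 controls 54 clusters differed, between the F0 and F3 controls 89, and between the F2 and F3 controls 40. All 36 pairs of libraries gave between 32 and 99 clusters, with a median of 64. A read can cover several dyads of a cluster, so these p-values are too small. Requiring 20 points lowered the 6 counts to between 18 and 42, and thinning to 10 reads per dyad left at most 1 cluster in any of the 6 comparisons.

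**Figure D3:**
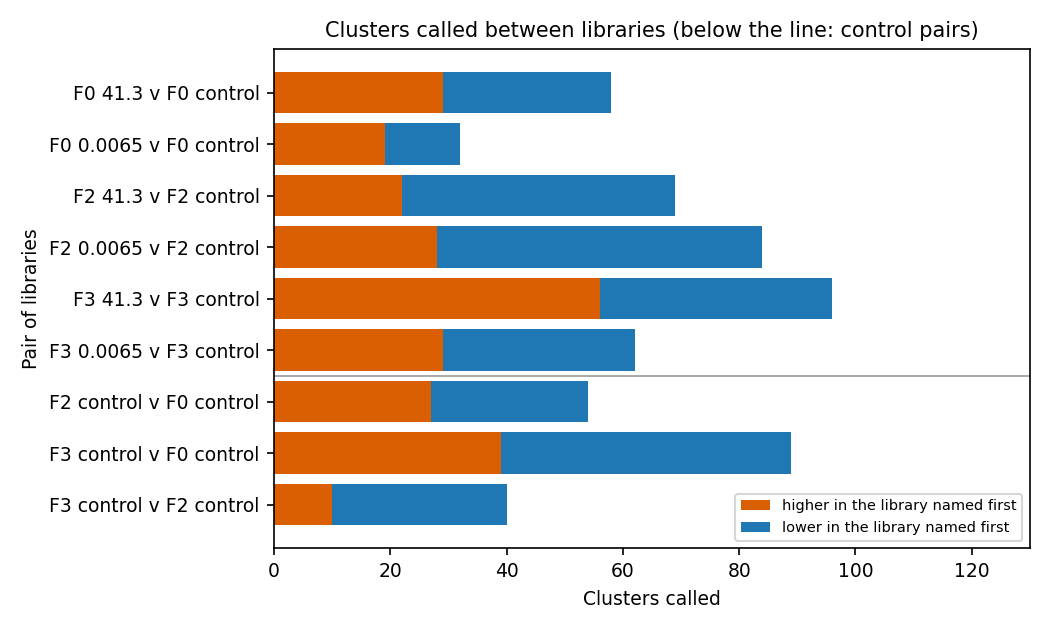
Number of clusters (horizontal axis) that differed by 10 points or more between 2 libraries at an adjusted p under 0.05, split into clusters higher and lower in the library named first. Comparisons with a control of the same generation gave 32 to 96 clusters and the 3 pairs of controls, below the line, gave 40 to 89.

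At the level of single dyads the pairs differed more. Between exposed and control libraries of the same generation, 12 dyads (F0 41.3 mGy/h), 81 (F0 0.0065 mGy/h), 114 (F2 41.3 mGy/h), 233 (F2 0.0065 mGy/h), 167 (F3 41.3 mGy/h) and 85 (F3 0.0065 mGy/h) differed by 20 points or more at an adjusted p under 0.05 in Fisher's exact test. The pairs of controls gave 56 dyads (F0 and F2), 76 (F0 and F3) and 0 (F2 and F3). No dyad differed between F0 41.3 and F2 41.3 mGy/h either, and 1 dyad did between F2 0.0065 mGy/h and the library labelled F3 41.3 mGy/h. At the level of clusters these pairs differed in 55 and 52 clusters, against the median of 64 over all pairs. Between F2 41.3 mGy/h and the library labelled F3 41.3 mGy/h 145 dyads differed. The library labelled F3 0.0065 mGy/h had 3 to 96 such dyads with the other libraries. It had the fewest calls (115459907), but the F2 control, with nearly as few (115619134), had 56 to 233 with all libraries except the F3 control. Thinned to 10 reads, none of the 6 comparisons with a control had a dyad left.

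**Figure D4:**
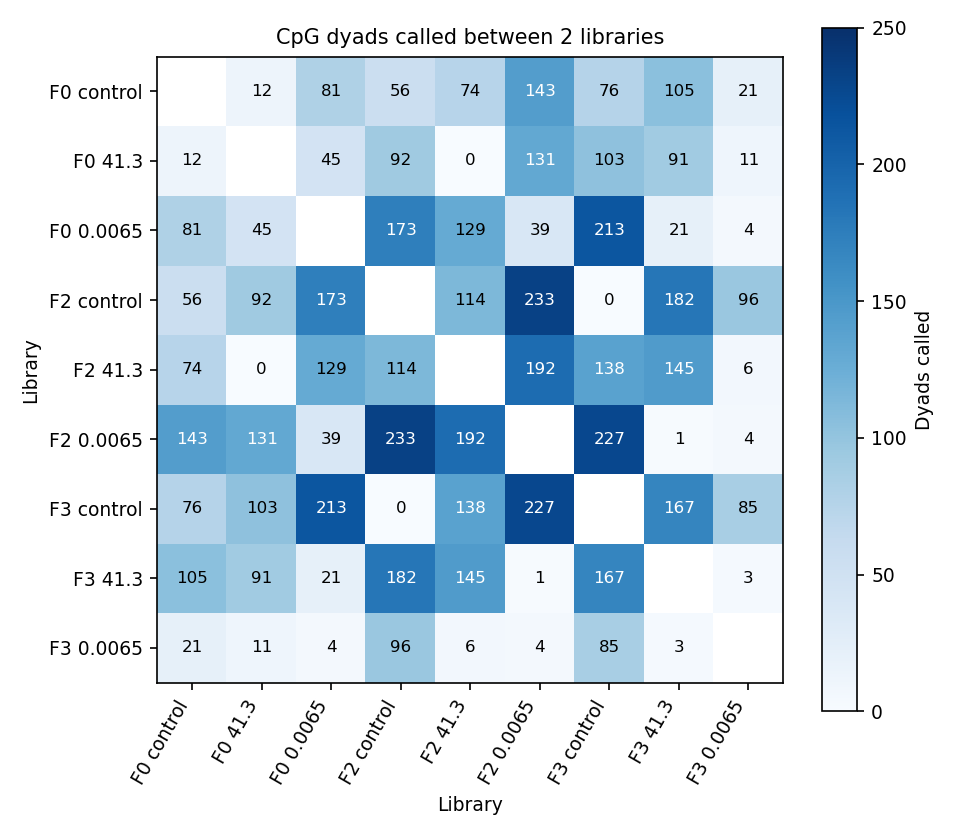
Number of CpG dyads that differed by 20 points or more at an adjusted p under 0.05 between each of the 36 pairs of libraries (both axes list the 9 libraries; darker cells hold more dyads). The F2 and F3 controls and the F0 and F2 41.3 mGy/h libraries had 0 such dyads, and F2 0.0065 mGy/h had 1 with the library labelled F3 41.3 mGy/h.

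Few clusters differed the same way in F2 and F3. At 41.3 mGy/h 6 clusters did (2 higher, 4 lower), where lists drawn independently would share 0.638. Another 1 went opposite ways, where independent lists would give 0.721. At 0.0065 mGy/h 5 clusters did, all lower, where independent lists would share 0.546. Another 2 went opposite ways, where independent lists would give 0.523. Independent lists take every cluster as equally likely to be called. The levels of the F2 and F3 controls, less the mean of their generation, correlated at 0.151 over clusters. Overlap against these controls can thus exceed that of independent lists without an effect of dose rate. No cluster differed the same way in F0, F2 and F3 at either dose rate. On scaffold00944, positions 1927456 to 1927619, the level was 92.7% and 91.5% in the F2 and F3 controls and 64.1 to 69.4% in the other 7 libraries, the F0 control included at 68.4%. A cluster on scaffold00024, positions 1105991 to 1106148, was also lower than control at both dose rates, with 95.2% and 95.9% in the F2 and F3 controls, 77.3 to 83.1% in the exposed F2 and F3 libraries and 85.8% in the F0 control. On scaffold02852, positions 260118 to 260128, the level was 58.1% in F2 and 65.3% in F3 at 0.0065 mGy/h and 83.3% or more in the other 7 libraries. On scaffold01877, positions 110795 to 110837, it was 27.7% in F2 0.0065 mGy/h, 34.3% and 34.6% in the libraries labelled F3 0.0065 and F3 41.3 mGy/h, and 57.9% or more elsewhere. The 2 clusters that were higher at 41.3 mGy/h lay on scaffold02902, positions 90375 to 90483, with 18.2% and 20.3% in the F2 and F3 controls against 39.6% and 37.0%, and on scaffold00868, positions 1843504 to 1843727, with 36.9% and 35.2% against 53.7% and 48.1%. The F0 control stood at 37.8% and 47.2% in these clusters. On scaffold02902 the library labelled F3 0.0065 mGy/h had the highest level of all libraries, 51.1%.

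Of the comparisons that crossed the dose rates, some shared more clusters than those of the same dose rate. F2 0.0065 mGy/h against control and the library labelled F3 41.3 mGy/h against control shared 15 clusters in the same direction, where independent lists would share 0.781, and 1 went opposite ways. F2 41.3 mGy/h and the library labelled F3 0.0065 mGy/h, each against its control, shared 5, and 3 went opposite ways. Each of these overlaps uses the F2 and F3 controls. Without the F2 control, F2 41.3 against 0.0065 mGy/h and the F3 control against the library labelled F3 41.3 mGy/h shared 11. Independent lists would share 0.927, and 2 went opposite ways. With the library labelled F3 0.0065 mGy/h in place of that F3 library, 2 were shared and 2 went opposite ways. Without a control, 41.3 against 0.0065 mGy/h as labelled in F2 and in F3 shared 1 cluster in the same direction, and 4 went opposite ways. At 20 points, 1 cluster was left at 41.3 mGy/h, with 1 going the opposite way, and 4 at 0.0065 mGy/h. The crossed comparison with 15 kept 8, that with 11 kept 6, and that with 5 kept 4, with 1 going the opposite way in the last. Thinned to 10 reads, 0 clusters were left at either dose rate.

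**Figure D5:**
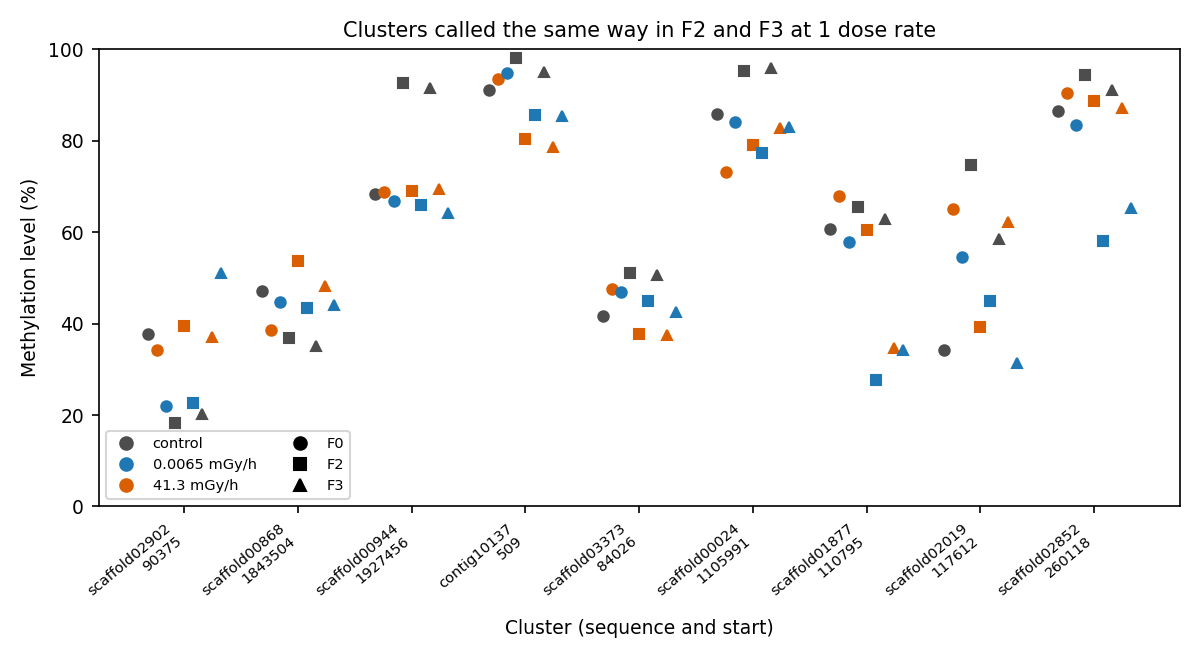
Methylation level in percent (vertical axis) of the clusters that differed from control the same way in F2 and F3 at 1 of the dose rates (horizontal axis, sequence and start position), with 1 point for each of the 9 libraries, coloured by dose rate and shaped by generation. On scaffold00944 the F2 and F3 controls lie at 92.7% and 91.5%, apart from the F0 control at 68.4%.

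With generations as the repeats of the dose rate comparison, no cluster passed the test. For 41.3 mGy/h against control, edgeR's quasi-likelihood test called 0 of 4874 clusters, with 256 at an unadjusted p under 0.05, and limma called 0, with 247. For 0.0065 mGy/h both called 0, with 267 and 268 clusters at an unadjusted p under 0.05, and for 41.3 against 0.0065 mGy/h both called 0, with 207 and 211. With no differences and a calibrated test, a share of 0.05 of the 4874 clusters would fall there. The clusters below were picked for the smallest p, so that the same direction in all generations is partly built in. The cluster nearest to the threshold at 0.0065 mGy/h lay on scaffold01745, positions 21772 to 21955, with 61.4% ± 3.21 (SD, n = 3 generations) against 79.1% ± 3.73 in the controls, lower in 3 of 3 generations (log2 odds ratio -1.27 ± 0.249 SE, edgeR adjusted p = 0.139). The same cluster had 64.4% ± 2.34 at 41.3 mGy/h (edgeR adjusted p = 0.458). A cluster on scaffold02190, positions 1587764 to 1587934, had 73.0% ± 1.51 at 0.0065 mGy/h against 87.1% ± 2.83 in the controls (edgeR adjusted p = 0.139), and a cluster on scaffold00655, positions 1548 to 1818, had 84.4% ± 2.57 against 92.9% ± 0.624 (edgeR adjusted p = 0.139). At 41.3 mGy/h the smallest p was in the scaffold00024 cluster above, with 78.4% ± 4.84 against 92.3% ± 5.66 (log2 odds ratio -1.76 ± 0.363 SE, edgeR adjusted p = 0.458). A cluster on scaffold02649, positions 73575 to 73737, had 55.3% ± 4.60 against 75.1% ± 8.17, and a cluster on scaffold00872, positions 117027 to 117158, had 62.7% ± 3.79 against 80.8% ± 3.15, both not past the threshold. Counts were simulated with these libraries' coverage, 200 changed clusters and an assumed spread of 0.2 on the natural logit scale between libraries. In them edgeR recovered 30.4% of changes of 10 points at 41.3 mGy/h, 87.7% of 20 points and 98.6% of 30 points. These shares hold for that spread and that number of changed clusters and need not hold in the real data.

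Leaving out the irradiated generation changed these calls. With F2 and F3 alone, 3 clusters were lower than control at 41.3 mGy/h, on scaffold00944 (log2 odds ratio -2.35, edgeR adjusted p = 0.0264), scaffold00024 (-2.33, adjusted p = 0.0297) and contig10137, positions 509 to 665 (-2.77, adjusted p = 0.0411). At 0.0065 mGy/h 3 were lower, on scaffold00944 (-2.63, edgeR adjusted p = 0.00525), scaffold00024 (-2.39, adjusted p = 0.0204) and scaffold02852 (-2.83, adjusted p = 0.0204). Without the F0 control alone, the same clusters were called, 3 at each dose rate. Both dose rates were then set against the same F2 and F3 controls, and these clusters were already among those that differed the same way in F2 and F3. With F2 and F3 alone these generations were the only repeats, though 0 dyads differed between their controls. A difference particular to the line of the controls would then count in both generations. The p-values therefore do not measure the spread between independent lines. On contig10137 the F0 libraries stood at 91.0% (control), 93.5% (41.3 mGy/h) and 94.8% (0.0065 mGy/h). Without the library labelled F3 41.3 mGy/h, 1 cluster differed between the dose rates, on scaffold01581, positions 2410358 to 2410550 (log2 odds ratio 2.23, edgeR adjusted p = 0.00780), and without both exposed F3 libraries 2 did. The level on scaffold01581 was 67.5% in F0 0.0065, 69.8% in F2 0.0065 and 72.6% in the library labelled F3 41.3 mGy/h, and 80.4 to 94.0% in the other 6 libraries.

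Between generations no cluster passed the test either. For F2 against F0 edgeR and limma each called 0 clusters, with 210 and 231 at an unadjusted p under 0.05. For F3 against F0 both called 0, with 239 and 251, and for F3 against F2 both called 0, with 193 and 209. A share of 0.05 of the clusters would fall there with no differences, and the clusters below were again picked for the smallest p. The cluster nearest to the threshold was on scaffold00687, positions 587705 to 587761, with 38.6% ± 3.94 in F3 (SD, n = 3 libraries of different dose rates), 60.4% ± 4.90 in F2 and 65.7% ± 6.11 in F0, lower in F3 than in F0 in 3 of 3 dose rates (log2 odds ratio -1.63 ± 0.289 SE, edgeR adjusted p = 0.0917). Another cluster of the same scaffold, positions 1072381 to 1072435, had 6.64% ± 3.43 in F3, 14.9% ± 1.15 in F2 and 16.7% ± 4.52 in F0 (edgeR adjusted p = 0.819 for F3 against F0). For F2 against F0 the smallest p was on scaffold02100, positions 15559 to 15674, with 44.4% ± 6.62 in F2 and 27.0% ± 4.05 in F0 (edgeR adjusted p = 0.989).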

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

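The differences in this part were not tested; each rests on 1 exposed and 1 control library per generation, and they were picked because 1 generation went the opposite way to the others.

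The overall level at 0.0065 mGy/h was above its control in F3, by 0.0686 points, while it was below control in F0 (-0.0824 points) and F2 (-0.150 points). At the methylated dyads the F0 library at 41.3 mGy/h was 0.0858 points above its control and the F0 library at 0.0065 mGy/h 0.611 points above, while the F2 and F3 libraries of both dose rates were below theirs, by -1.55 and -0.219 points at 41.3 mGy/h and by -1.80 and -0.801 points at 0.0065 mGy/h. In F2 both differences share the F2 control, which had the highest level of the 9 libraries. The number of dyads called methylated at 41.3 mGy/h was higher than in the control by 199 in F0 and differed by -176 in F2 and -325 in F3. At 0.0065 mGy/h it differed by -351 in F3 and was higher by 20 in F0 and 239 in F2.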

How the results depend on the processing

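The background subtraction, the equal weighting of methylated dyads, the omission of both exposed F3 libraries and the omission of each generation or dose class from the level differences were chosen after the results were seen; the other settings were planned. The 41.3 and 0.0065 mGy/h differences in overall level kept their negative sign under all settings tried, from -0.111 to -0.00210 points and from -0.116 to -0.00354 points, though not in each generation. The F2 and F3 differences from F0 changed sign with equal weights and the background rate subtracted together, to -0.00197 and -0.000582 points, and with neither alone (0.0841 and 0.105, 0.0795 and 0.0747 points). At the methylated dyads they changed sign with equal weights, to -0.179 and -0.0153 points, and the cause was not tested; with each dose class left out in turn, F2 minus F0 ran from -0.200 (without the controls) to 1.00 points. The number of dyads called methylated changed sign with dyads thinned to 10 reads, to +1249 at 41.3 mGy/h and +1202 at 0.0065 mGy/h. The threshold in whole reads accounts for this: 2 methylated reads sufficed in the exposed F0 libraries, with the lowest background rates, and 3 were needed in the other 7. With each generation left out in turn these differences ran from -250.5 to 11.5 and from -165.5 to 129.5 dyads, positive without F3. With a level of 20% and no test, F2 minus F0 became +15.3 dyads; the cause was not tested.

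Counts of clusters in the pairs with control, in the order F0 41.3, F0 0.0065, F2 41.3, F2 0.0065, F3 41.3 and F3 0.0065 mGy/h, were 34, 18, 34, 42, 39 and 32 at 20 points and 1, 0, 0, 1, 0 and 0 with dyads thinned to 10 reads, which removes most reads. With a coverage minimum of 20 the F0 0.0065, F2 0.0065 and F3 41.3 mGy/h counts became 21, 48 and 55, with fewer dyads tested. Gaps of up to 50 bp gave 53 for F0 0.0065 and 45 for F2 41.3 mGy/h, and 5 or more dyads per cluster gave 41 for F3 0.0065 mGy/h; the cause was not tested. Dyads differing in F0 at 41.3 mGy/h numbered 21 with a coverage minimum of 20, and thinned to 10 reads all 6 counts of dyads were 0. Clusters shared by F2 and F3 numbered 1 at 41.3 mGy/h with 20 points, and 0 at both dose rates when thinned.

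In the models, leaving out each library in turn gave 0 to 3 clusters at 41.3 mGy/h, 0 to 3 at 0.0065 mGy/h and 0 to 1 between the dose rates, the 3s without the F0 control and the 1 without the library labelled F3 41.3 mGy/h; for the 3 generation contrasts it gave 0. A left-out library leaves its group empty, and the fit then rests on the spread of the other groups. F2 and F3 alone gave 3 clusters at each dose rate. Both exposed F3 libraries left out gave 2 clusters between the dose rates, on scaffold01581 and on scaffold00243, positions 517076 to 517299. The counts of 0 did not change with limma, without the block, with coverage minimums of 5 or 20, gaps up to 200 bp, a pooled level of 20%, or thinned.

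Over the named clusters and the planned settings run for them, 460 combinations kept direction and side of the threshold. Another 58 kept the direction and lost the threshold, 53 of them when thinned, 4 gained it and 0 reversed, and in 18 no cluster overlapped. Of the 460, 268 were model clusters with 1 library left out, which stayed short of the threshold. Named clusters of the pairs were run only with coverage minimums of 5 and 20 and thinned, where 54, 33 and 2 stayed called. They were picked for large differences in the same reads, so that a reversal was unlikely beforehand. Tests of gene lists were not run for want of an annotation on these coordinates. A difference of 10 points in a cluster was mostly below what this depth detects in a pair of libraries.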

Other observations

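The test of exchanged labels with the correlations between generations, the comparison of the mixture with the F3 control and the splits of the libraries were chosen only after the result was seen; the other tests in this part were written down before their result.

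The methylated dyads were unevenly placed. Cytosines in the CGA context lay in methylated dyads more often than those in CGC, at 1.25% (interval 1.23 to 1.26) against 0.860% (0.845 to 0.876), with CGG at 1.07% and CGT at 1.18%. Among the largest sequences the share of methylated dyads was highest on scaffold02452, at 2.33%, and scaffold00725, at 2.02%, and lowest on scaffold03025, at 0.675% (0.577 to 0.784), against 1.12% over all tested dyads. The range of a cluster over the 9 libraries, which includes counting error, had a median of 9.88 points and a 95th percentile of 24.4 points, where 57.6% of the 4874 clusters had a mean level of 80% or more.

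For the 5270 dyads with pooled levels of 40 to 50%, a sequence variant of 1 allele at the dyad itself would leave its neighbours unaffected, but 83.0% (81.6 to 84.3) of their nearest methylated dyads within 50 bp also lay at 30 to 60%, against 4.41% next to dyads at 80% or more. Duplicated copies read on the same sequence would raise the depth, but the median depth relative to dyads at 80% or more was 0.997. Different states in different animals of a pool would spread the libraries apart, but the variance between libraries was 1.03 times that at dyads of 80% or more. Only pools of over 163 animals would have kept it below the bound of 1.2 times written beforehand, and the labels do not give the number of animals. Methylation of 1 of the 2 alleles, or of some cell types of the whole animal, may underlie these regions and was not tested.

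The background rate was 0.359% in the F0 libraries and 0.455% in the 6 F2 and F3 libraries, each of these above each F0 library, while the unweighted level less background was 0.812% and 0.810%. Sparse methylation around methylated regions would concentrate the excess there, but the factor within 1 kb of methylated dyads was 0.995 times that over 10 kb away. Over 10 kb from any methylated dyad the rate in F2 and F3 was 1.27 times that in F0, as lower conversion or more base errors in F2 and F3 would give. A technical cause is thus a candidate explanation of the higher unweighted level in F2 and F3 (by 0.0841 and 0.105 points), while the rest of the read-weighted difference (0.166 and 0.181 points) rested on read weighting, with a relative depth at methylated dyads of 0.924 to 0.965 in F0, 1.16 in the F2 control, 1.12 in the library labelled F3 0.0065 mGy/h and at most 0.991 in the other exposed F2 and F3 libraries. A sparse genome-wide gain of methylation would look the same as a technical cause and stays open, since no conversion control was analysed here and generation and library preparation may go together.

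At the 192 dyads that differed between F2 41.3 (position 0) and F2 0.0065 mGy/h (position 1), F0 41.3 mGy/h lay at 0.283 and F0 0.0065 mGy/h at 0.739, the 3 controls at 0.390 to 0.436, the library labelled F3 41.3 mGy/h at 0.868 (interval 0.830 to 0.908) and the library labelled F3 0.0065 mGy/h at 0.512 (0.473 to 0.546). The dyads were picked for the difference between the 2 end libraries in the same reads. This enlarges that difference and draws the other libraries towards the middle, which the intervals do not cover. In the same way the F3 control lay at 0.135 from the F2 control towards either exposed F2 library, though 0 dyads differed between these controls. Exchanged labels of the exposed F3 libraries stay open. Correlations of cluster deviations, centred within each generation, summed to 0.351 between F2 and F3 with these labels exchanged and 0.102 as given. The controls gave 0.151 of both sums. As given, the exposed libraries correlated at -0.0163 (0.0065 mGy/h) and -0.0324 (41.3 mGy/h). Crossed, F2 0.0065 with F3 41.3 mGy/h gave 0.119, and F2 41.3 with F3 0.0065 mGy/h gave 0.0812. Between F0 and F3 the sums were 0.0771 exchanged and -0.0683 as given, but there another assignment was highest (0.0952). F0 with F2 was highest as given (0.113). The library labelled F3 0.0065 mGy/h differed in 6 dyads from F2 41.3 and 4 from F2 0.0065 mGy/h. From the F2 control it lay at 0.649 towards the former and 0.675 towards the latter. Sequence variants at the 192 dyads would not move their neighbours. Of these dyads, 99 had a methylated dyad within 50 bp, and these neighbours moved by 47.9% (35.8 to 59.1) as much. A mean of this size cannot exclude variants at a part of the dyads. The neighbour could itself be 1 of the 192, and dyads without such a neighbour were not covered. DNA of both kinds of descent in the library labelled F3 0.0065 mGy/h also stays open: its residual variance around a mixture was 1.94, above the simulated range of 0.865 to 1.37, and by this bound, set beforehand, the mixture would be excluded, but that range allowed no change between F2 and F3, and the F3 control, set against F2 libraries in the same way, had 2.11 and 2.29. Labels were kept as given, a single wrong label stays open too, and differences between lines of descent that arose without radiation may account for differences between dose rates, since the lines are not given in the labels and the design cannot separate them.

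For the clusters called by the models, the 6 libraries of each contrast can be split in only 10 ways, too few for a share under 0.05; the real count was 0 in each. The highest count of another split was 0 for 41.3 mGy/h against control, for 0.0065 mGy/h against control, and for F2 against F0, F3 against F0 and F3 against F2. For 41.3 against 0.0065 mGy/h it was 3, in the split that exchanges the exposed F3 libraries.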
